A study of Synechocystis sp. PCC 6803 with 4 samples.

How the data were processed

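Transcript levels of the cyanobacterium Synechocystis sp. PCC 6803 were measured on CyanoChip, a spotted cDNA microarray that carries 2 spots per gene. The glucose-tolerant wild type (GT) was compared with an ntcA-overexpressing strain (NOX10), with 2 samples of each. Per the labels' protocols, cells were grown in modified BG-11 medium with 5 mM NH4Cl, moved to medium lacking a nitrogen source and kept there for 4 h at 50 to 70 micromoles of photons per square metre per second. Per the same protocols, total RNA was isolated with hot phenol and labelled cDNA was made with the Takara RNA Fluorescence Labeling Core Kit. Both GT samples carried Cy3 and both NOX10 samples carried Cy5, so that dye and genotype cannot be separated in any comparison. The series' design text calls the strains independent, and no label says whether the samples came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

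The deposited values were spot intensities on a linear scale, 1 value per spot and 2 spots per gene, per the file headers. The scanner, the image software, the background treatment and any spot filter are not given in the sources used here. The 24592 spot intensities ranged from 53 to 65196 and 0 of them lay at or below 0, so they were treated as not corrected for background. The deposited series table held intensities too. Its values came within 0.563% of those obtained by scaling each spot column to a mean of 3253.09 and averaging the 2 spots of a gene. Its column medians were 1795 and 1810.5 in GT and 1782 and 1799.5 in NOX10, and neither log transformation nor centring of genes was found in it. For 16 genes the deposited NOX10 intensities were not whole numbers, which applied to 2 of them in GT as well. Such values were computed by the authors in a way not given in the sources used here. None of these genes passed the main threshold, and 3 of them (bicA, gap2 and rplJ) were in the gene lists.

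The background of each spot column was corrected with the normexp model with an offset of 50, on the spot intensities alone. Values were log2-transformed, the 2 spots of a gene were averaged, and the 4 samples were quantile-normalized. All 3074 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, with neither intensity trend nor robust hyperparameters). There were 2 residual degrees of freedom per gene and 5.68 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are NOX10 over GT on the log2 scale after the offset, which understates the change of dim genes, and errors are the standard errors (SE) of the moderated fit. The number of arrays limits the precision. The median SE over all genes was 0.23.

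Gene lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 23 lists. Camera with an estimated correlation, and fry, were run beside it. With an estimated correlation camera rests on the residual degrees of freedom, 2 per gene in the main fit. Few degrees of freedom limit its power, which was not simulated, so a list that it does not call is not thereby contradicted. The lists together with ntcA held 263 genes, of which 261 were on the array. The files pair no gene symbols with locus tags. The RefSeq table used here carries other locus tags, with 0 rows of the array's kind, although 142 of the 263 list symbols occur in it. Symbols are therefore printed only for list genes, whose pairing with a locus tag is common usage for this strain and comes from no file. The membership of the lists likewise comes from no file. Genome coordinates were not used here.

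The groups, the lists, the tests of the comparison and the alternatives were fixed before the data were examined, apart from the alternatives named below as added. Tests of technical explanations came later, some of them after the results were seen, as the closing section states. The rule for named genes took ntcA, then the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap. It also took the 2 members of each list with the smallest p, every list member that passed, and any member of a list with 6 or fewer measured genes. Of the 20 genes of the largest changes, only those with a list symbol and 2 further locus tags per direction are printed, fewer than the rule takes. These tags are those of the largest changes among the unlisted genes. No table names them or the loci left out.

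The labels give both groups replicate numbers 1 and 2, and the differences between their spots were examined before any fit. Across genes, the log difference between the 2 spots had a Pearson r of 0.579 between GT 1 and NOX10 1 and of 0.788 between GT 2 and NOX10 2. The 4 other pairs of samples gave r between -0.170 and -0.104. Genes are not independent replicates, and these values describe the spots only. Samples of the same number thus shared a pattern between spots, as samples hybridised to a single array would, although the labels do not state it. Deviations from the group means had an r of 0.226 between samples of the same number. A fit with the replicate number as a block was run as an alternative, and its values stand beside the main ones where they change a call.

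Other alternatives were no background correction, no offset, an offset 4 times larger, median scaling, cyclic loess, and a loess of Cy5 over Cy3 within each replicate number together with the block. Further ones were leaving out the dimmest 25% of genes, the first or the second spot alone, eBayes with a trend or robust, the series table, another threshold, and leaving out each sample. Leaving out the 16 genes with computed values and no normalization between samples were added after seeing the data. So were list tests with an estimated correlation in the blocked fit.

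The fit was tested on simulated data of 3074 genes in 2 against 2 samples, with 200 genes changed in each of 5 runs. It called a median of 94% of genes changed by a log2 fold of 2 and 26% of those changed by a log2 fold of 1. A median of 5 of 2874 unchanged genes were called. With camera at the preset correlation a shifted list was called in 5 of 5 runs, and 0 unshifted lists were called. The simulated genes varied independently of each other, and no simulated samples shared an array. In the data the estimated correlation between genes was 0.73 in the hydrogenase list. The runs therefore cannot show how often a list of correlated genes is called without a shift.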

Results

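Expression of 3074 genes was measured in 4 samples of Synechocystis sp. PCC 6803 after 4 h without nitrogen, 2 of the glucose-tolerant wild type GT and 2 of the ntcA-overexpressing strain NOX10. NtcA is the global transcriptional regulator of nitrogen assimilation in cyanobacteria, and the comparison asks which transcripts differ when its gene is overexpressed in nitrogen-depleted cells. Summed intensities of the first and second spots were 7491404 and 5234971 in GT 1 and 5833924 and 5278769 in GT 2. In NOX10 they were 7169072 and 4698702 in sample 1 and 6255053 and 5601704 in sample 2. Median spot intensities lay between 822 and 1360, and the log2 intensities of the 2 spots correlated across genes with r between 0.963 and 0.979.

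The overexpressed gene ntcA (sll1423) rose 6.29-fold in NOX10, a log2 fold change of 2.65 ± 0.21 (SE, n = 2 per group) with a limma adjusted p of 0.00494. Its normalized intensities were 2416 and 2451 in GT and 15670 and 14960 in NOX10. The gene of isocitrate dehydrogenase, icd (slr1289), which supplies 2-oxoglutarate for ammonium assimilation, rose by 2.11 ± 0.23. The gene of the glutamine synthetase inhibitor IF7, gifA (ssl1911), fell by 2.22 ± 0.35, and the phosphoribulokinase gene prk (sll1525) of the Calvin cycle fell by 1.74 ± 0.24. With the replicate number as a block, gifA had an adjusted p of 0.0561 and the other 3 genes passed.

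In all, 65 genes were higher and 58 lower in NOX10 at an adjusted p under 0.05. In each of these 123 genes both NOX10 values lay on one side of both GT values, which the call itself makes likely. The same was so for 53.4% of all genes, against 33.3% by chance if samples were exchangeable. An effect of dye would raise that share as one of genotype would. The smallest absolute log2 fold change among the 123 genes was 0.96, and the medians were 1.40 for the higher and -1.34 for the lower genes. The largest rises included ntcA and icd and the unlisted loci sll1080 (2.98 ± 0.34) and slr1681 (2.82 ± 0.25). The largest falls included gifA and the loci slr1452 (-3.03 ± 0.53) and ssr2439 (-2.30 ± 0.36). With replicate number as a block 27 genes were higher and 20 lower, all 47 of them among the 123, and ntcA, icd, nrrA, sigH, prk and atpH passed among the called list genes. Genotype coincided with dye, and without GT 1 or without GT 2 limma called 0 genes in either direction (ntcA adjusted p = 0.25 and 0.282), against 270 higher and 276 lower, or 236 and 253, at an unadjusted p under 0.05. Higher and lower counts were 45 and 37 without NOX10 1, 6 and 0 without NOX10 2 (203 and 195 unadjusted), 37 and 26 after cyclic loess, 7 and 1 with the first spot alone, and 0 and 0 with the second spot alone (259 and 252 unadjusted).

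**Figure D1:**
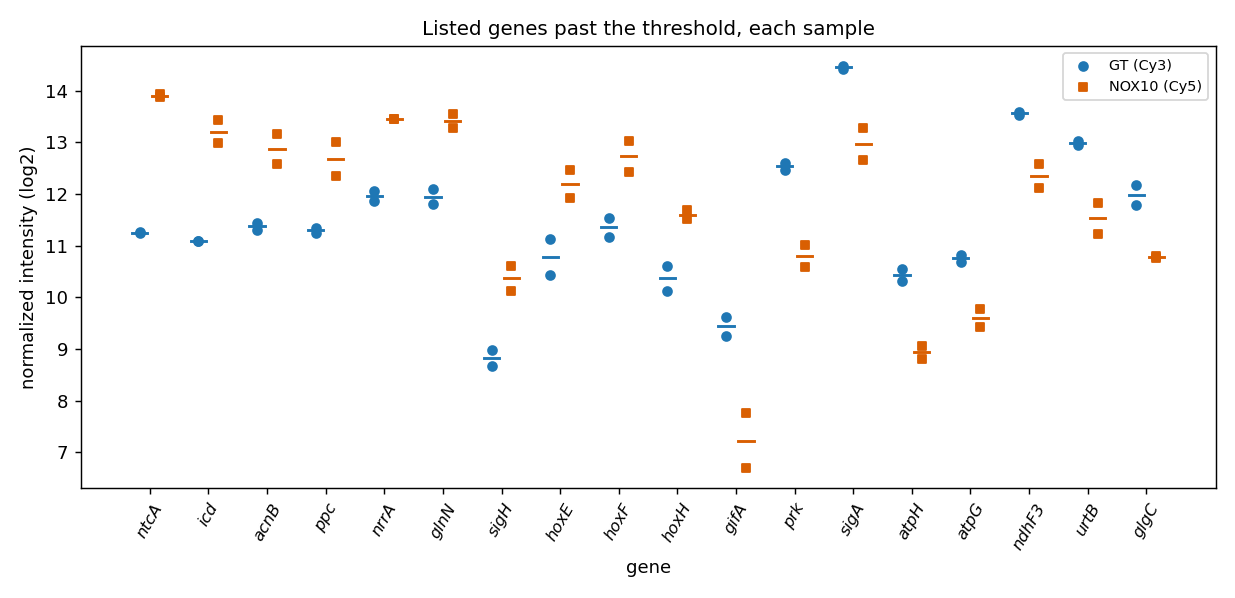
Normalized log2 intensity of each list gene past the threshold, in each sample; circles are the 2 GT samples, squares the 2 NOX10 samples and bars the group means. ntcA lies at 11.25 in GT and 13.90 in NOX10 on average, and in each gene both samples of a group lie on the same side of both samples of the other.

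**Figure D2:**
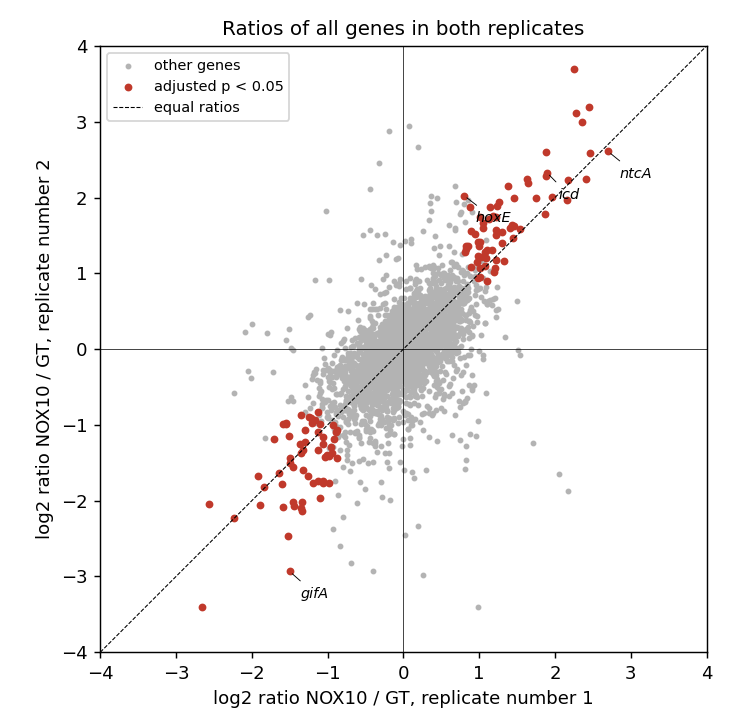
Log2 ratio of NOX10 over GT for each of the 3074 genes in replicate number 1 (horizontal axis) and 2 (vertical axis); points are genes, red where the adjusted p is under 0.05, and the dashed line marks equal ratios. The ratios correlate across genes with r = 0.611, genes not being independent replicates, and have the same sign in 72.3% of genes.

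Among 20 measured genes of nitrogen assimilation listed here as activated by NtcA, 3 rose, 0 fell and 17 did not pass. Adjusted over the list alone, 4 were higher and 2 lower. The genes that rose were icd, the response regulator gene nrrA (sll1330; 1.5 ± 0.21, adjusted p = 0.0147) and glnN (slr0288; 1.47 ± 0.23, adjusted p = 0.0210), which encodes a type III glutamine synthetase. The main glutamine synthetase gene glnA (slr1756) had a log2 fold change of -1.01 ± 0.22 and an adjusted p of 0.0517. With the replicate block glnN had an adjusted p of 0.0507. The list as a whole did not pass (camera adjusted p = 0.174), with an adjusted p of 0.715 with an estimated correlation and of 0.35 with the replicate block. With the preset correlation its adjusted p was 0.0036 without NOX10 1, shifted up, and 0.822 without NOX10 2, each with a single NOX10 sample. The nitrate transporter gene nrtA (sll1450) and the nitrite reductase gene nirA (slr0898) had log2 fold changes of 1.34 ± 0.67 and 1.06 ± 0.54 and did not pass.

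All 4 genes listed here as repressed by NtcA had negative fold changes, of which gifA fell and 3 did not pass. Adjusted over the list alone, 2 were lower. The second inhibitor gene, gifB (sll1515), had a log2 fold change of -1.66 ± 0.50 (adjusted p = 0.114). The values of pirA (ssr0692) and gdhA (slr0710), the glutamate dehydrogenase gene, were -0.50 ± 0.35 and -0.21 ± 0.21. The list was shifted down (camera adjusted p = 0.0341). Its adjusted p was 0.715 with an estimated correlation, 0.0802 with the replicate block and 0.346 in fry's directional test. The list did not pass without GT 1, GT 2 or NOX10 2. Without the dimmest 25% of genes its camera adjusted p was 0.146. That setting may have left out gifA, whose mean log2 intensity was 9.44 in GT and 7.22 in NOX10. The value therefore need not describe all 4 genes.

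Of 10 genes of the TCA cycle and its filling reactions, 3 rose and 7 did not pass, while 4 were higher when adjusted over the list alone. With icd these were the aconitase gene acnB (slr0665; 1.5 ± 0.26) and the phosphoenolpyruvate carboxylase gene ppc (sll0920; 1.38 ± 0.27). The citrate synthase gene gltA (sll0401) had a log2 fold change of 0.99 ± 0.23 and an adjusted p of 0.0586. With the replicate block acnB and ppc had adjusted p of 0.0545 and 0.0568. The list was shifted up (camera adjusted p = 0.0307). Its adjusted p was 0.715 with an estimated correlation, 0.0802 with the replicate block and 0.237 in fry's directional test. Without GT 1, GT 2 or NOX10 2 its adjusted p was 0.0863, 0.101 and 0.0502.

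The 5 measured genes of the bidirectional hydrogenase all had positive fold changes with a median of 1.37. Of these hoxE (sll1220; 1.41 ± 0.30), hoxF (sll1221; 1.37 ± 0.28) and hoxH (sll1226; 1.23 ± 0.25) rose. The remaining hoxU (sll1223; 1.35 ± 0.31) and hoxY (sll1224; 1.41 ± 0.35) had adjusted p of 0.0541 and 0.0690. Adjusted over the list alone, 5 were higher. At the preset correlation the list was shifted up (camera adjusted p = 0.000306). The correlation estimated between its genes was 0.73, far above the preset one, so that this p may overstate the evidence. With the estimated correlation the adjusted p was 0.715, and in fry's directional test it was 0.237. With the replicate block none of its 3 called genes passed (adjusted p = 0.0850, 0.0746 and 0.0622 for hoxE, hoxF and hoxH). In that fit the list had a camera adjusted p of 0.00310 at the preset correlation and of 0.872 with an estimated one.

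Of 8 measured ATP synthase genes, 2 fell and 6 did not pass; adjusted over the list alone, 6 were lower. The genes that fell were atpH (ssl2615; -1.5 ± 0.22) and atpG (sll1323; -1.16 ± 0.23), which encode subunits of the membrane part of the enzyme. With the replicate block atpG had an adjusted p of 0.0512. The next smallest p belonged to atpF (sll1324), with -1.10 ± 0.26 and an adjusted p of 0.0614. At a separate pair of loci, atpB (slr1329) and atpE (slr1330) had fold changes of -0.41 ± 0.21 and 0.17 ± 0.25. At the preset correlation the list was shifted down (camera adjusted p = 0.000857). The correlation estimated between its genes was 0.473, far above the preset one, so that this p may overstate the evidence. With the estimated correlation the adjusted p was 0.715, and in fry's directional test it was 0.237.

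Among 23 genes of inorganic carbon concentration, Rubisco and carbon fixation, 2 fell and 21 did not pass, while 6 were lower when adjusted over the list alone. Besides prk, ndhF3 (sll1732; -1.21 ± 0.24), which encodes a subunit of an inducible CO2 uptake complex, fell (adjusted p = 0.0545 with the replicate block). The Rubisco genes rbcL (slr0009) and rbcS (slr0012) had fold changes of -0.81 ± 0.22 and -0.86 ± 0.21, with adjusted p of 0.0815 and 0.0697. The list was shifted down (camera adjusted p = 0.00505). Its adjusted p was 0.715 with an estimated correlation and 0.237 in fry's directional test. At the preset correlation it did not pass without GT 1.

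In photosystem II 0 of 25 genes passed, 19 had positive values and the median was 0.27. The smallest p belonged to psbD (sll0849; 0.90 ± 0.22, adjusted p = 0.0673) and psbD2 (slr0927; 0.80 ± 0.22, adjusted p = 0.0834), which encode the reaction centre protein D2. Their normalized intensities in GT were alike, 13330 and 10780 for psbD and 12940 and 10860 for psbD2. Whether the spots tell these genes apart was not tested. The list was shifted up (camera adjusted p = 0.0355). In fry's directional test its adjusted p was 0.346, and in camera with an estimated correlation it was 0.715. Its adjusted p was 0.169 without GT 2, 0.258 without NOX10 1 and 0.138 with no normalization between samples. In photosystem I 0 of 12 genes passed over all genes and 2 were lower when adjusted over the list alone, namely psaM (smr0005; -1.08 ± 0.24) and psaD (slr0737; -0.93 ± 0.22). The photosystem I list did not pass (camera adjusted p = 0.138), with an adjusted p of 0.0419 without NOX10 1 and of 0.715 with an estimated correlation over all samples.

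**Figure D3:**
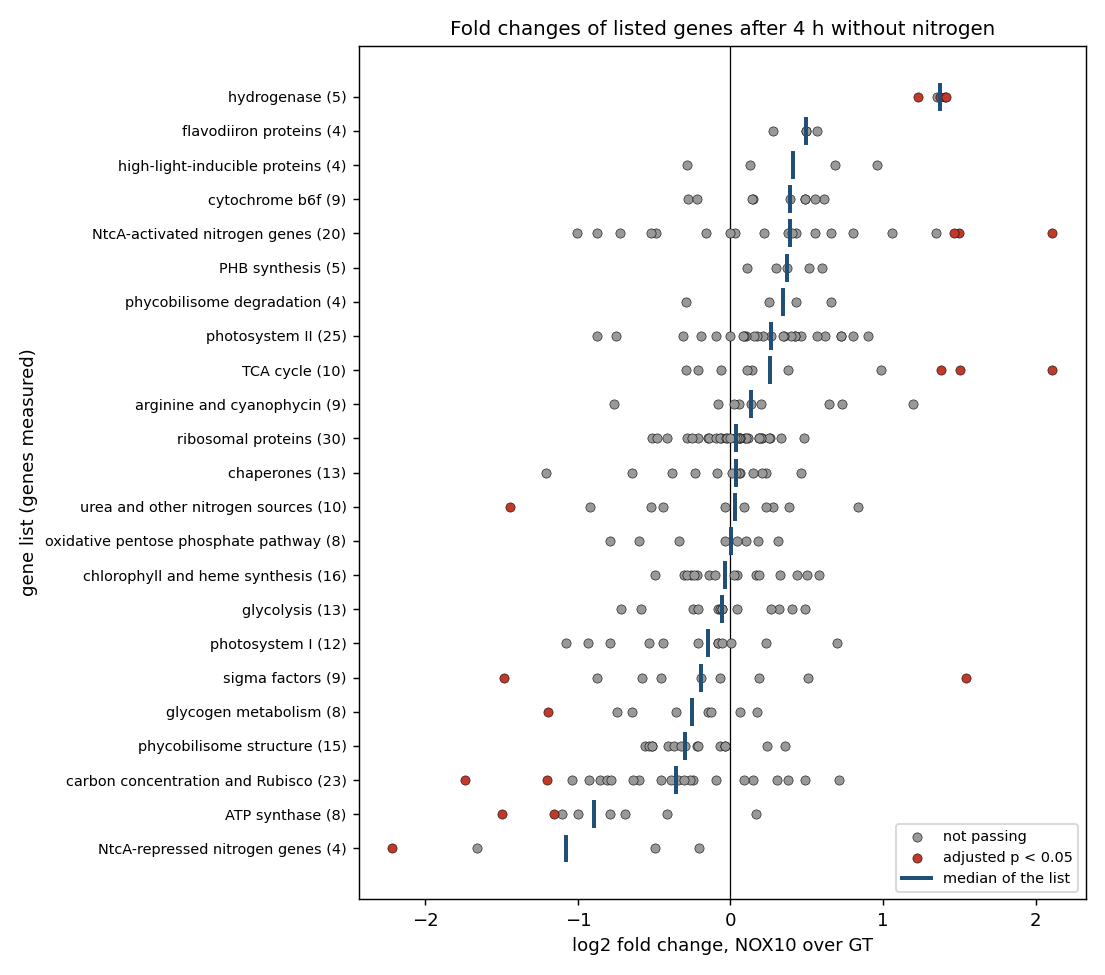
Log2 fold change (NOX10 over GT) of every measured gene in the 23 lists, with the number of genes in parentheses; points are genes, red where the adjusted p is under 0.05, and bars are list medians. The medians run from -1.08 in NtcA-repressed genes to 1.37 in hydrogenase genes.

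Among 9 sigma factor genes, sigH (sll0856) rose by 1.55 ± 0.25 (adjusted p = 0.0243) and the principal sigma factor gene sigA (slr0653) fell by 1.48 ± 0.26 (adjusted p = 0.0307). The group 2 sigma factor gene sigE (sll1689), a known NtcA target, had a fold change of -0.87 ± 0.31 and did not pass (adjusted p = 0.162). Among 8 genes of glycogen metabolism, the ADP-glucose pyrophosphorylase gene glgC (slr1176) fell by 1.2 ± 0.23 (adjusted p = 0.0366) and 7 did not pass. Among 10 genes of urea and other nitrogen sources, the urea transporter gene urtB (slr1200) fell by 1.45 ± 0.26 (adjusted p = 0.0310), and 9 did not pass. In that list 2 genes were lower when adjusted over the list alone, the second being urtC (slr1201; -0.92 ± 0.26). Adjusted over the list alone, 1 sigma factor gene was higher and 1 lower, and 1 glycogen gene was lower. With the replicate block the adjusted p was 0.0507 for sigA, 0.0547 for glgC and 0.0507 for urtB. None of these lists passed as a whole, with camera adjusted p of 0.515 for sigma factors, 0.158 for glycogen metabolism and 0.492 for the urea list. Without NOX10 2 the glycogen list had an adjusted p of 0.0407, against 0.715 with an estimated correlation over all samples.

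In the remaining lists 0 genes passed, over all genes or over the list alone, and 0 lists passed. Camera adjusted p was 0.0803 for the 4 flavodiiron genes, 0.138 for 5 PHB synthesis genes, 0.138 for 15 structural genes of the phycobilisome and 0.195 for 9 cytochrome b6f genes. It was 0.423 for 9 genes of arginine and cyanophycin metabolism, 0.515 for 4 high-light-inducible genes, 0.533 for 4 phycobilisome degradation genes and 0.533 for 8 oxidative pentose phosphate genes. It was 0.826 for 13 glycolysis genes, 0.826 for 13 chaperone genes, 0.948 for 30 ribosomal protein genes and 1.0 for 16 genes of chlorophyll and heme synthesis. The flavodiiron genes all had positive values, from 0.28 for flv3 (sll0550) to 0.57 for flv1 (sll1521), and were the one list past the threshold in fry's test for changes in either direction (adjusted p = 0.0134), while fry's directional test gave an adjusted p of 0.0505. Their camera adjusted p was 0.0456 with no background correction, 0.0376 with the larger offset and 0.0433 with the first spot alone, against 0.715 with an estimated correlation in the main setting. Without NOX10 1 the adjusted p was 0.0419 for structural genes of the phycobilisome, 0.0038 for ribosomal proteins and 0.0239 for chaperones, all shifted down. Without NOX10 2 the ribosomal protein list was shifted up (adjusted p = 0.0047). With an estimated correlation over all samples the adjusted p was 0.715 for the phycobilisome list, 1.0 for ribosomal proteins and 0.993 for chaperones. The median and the mean differed in sign for the urea list (0.027 and -0.15), the oxidative pentose phosphate list (0.0031 and -0.14), chlorophyll and heme synthesis (-0.038 and 0.014), ribosomal proteins (0.035 and -0.0026) and chaperones (0.034 and -0.10). Camera's direction followed the mean in each.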

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

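Leaving out the 16 genes with computed values and no normalization between samples were chosen after seeing the data. So were the list tests with an estimated correlation within the replicate block. The other alternatives were planned. All 123 called genes kept their direction in each alternative in which they were tested. These settings reuse the same samples, in which the groups of each called gene did not overlap, so a reversal was unlikely in advance. Counts of calls moved by over 1.5 times with cyclic loess (37 higher and 26 lower), with the replicate block (27 and 20), with the first spot (7 and 1) and with the second spot (0 and 0, or 259 and 252 at an unadjusted p under 0.05). With no normalization 95 genes were higher and 99 lower. With an adjusted p under 0.1 there were 139 higher and 134 lower genes. By at least 2-fold with no overlap, 87 were higher and 92 lower. With one sample left out, counts ranged from 0 to 45 higher and 0 to 37 lower. The cause was not tested, except that leaving out a sample leaves fewer samples, the lone one being assumed to vary like the other group. The 35 called genes taken by the rule for named genes kept their direction in 519 of 519 comparisons over genes and settings and their call in 422. With one sample left out they kept their direction in 140 of 140. That was nearly fixed in advance, because the groups of each called gene did not overlap in the main fit. The ntcA log2 fold change ranged from 2.61 to 2.71 with one sample left out, and with the second spot it was 2.62 (adjusted p = 0.0540, over a range from 1.73e-06 to 0.282). Of the 20 genes of the largest changes, 7 passed with the first spot, 0 with the second, and 0 to 20 with one sample left out. The number of lists called ranged from 3 to 10 with one sample left out. It was 0 with an estimated correlation, 0 with fry's directional test and 0 with an estimated correlation in the replicate block. Camera with an estimated correlation rests on the residual degrees of freedom, 2 in the main fit. Its power was not simulated, and with so few degrees of freedom it cannot decide for or against a list. Its adjusted p was 0.715 both for NtcA-repressed genes (estimated correlation -0.0246) and for hydrogenase genes (0.73). For fry the cause was not tested. The hydrogenase, ATP synthase and carbon lists each passed in the 15 other settings that kept all samples, all of them at the preset correlation. At the preset correlation the replicate block changed no call of a list other than the NtcA-repressed and TCA lists.

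The direction of uncalled lists reversed in some settings (camera adjusted p): chlorophyll and heme synthesis with no offset (0.972), the second spot (0.919) and the 16 genes left out (0.999), ribosomal proteins with median scaling (0.930), the first spot (0.951) and no normalization (0.881), and glycolysis with the 16 genes left out (0.999). With one sample left out, directions reversed and adjusted p ranged from 0.451 to 0.803 for glycolysis, 0.731 to 0.803 for chlorophyll and heme synthesis, 0.0038 to 0.405 for ribosomal proteins, 0.0239 to 0.405 for chaperones, 0.0753 to 0.803 for the urea list, 0.0729 to 0.785 for phycobilisome degradation and 0.0729 to 0.982 for high-light-inducible genes. Log2 fold changes of uncalled genes then ranged from -0.46 to 0.72 for hliB (ssr2595), -0.17 to 0.39 for phaE (slr1829), -1.04 to 0.049 for pirA, -0.30 to 1.16 for nblA2 (ssl0453) and -0.098 to 1.47 for hliA (ssl2542). Signal over background could not be measured, because no background columns were used here.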

Other observations

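The tests of dye bias with intensity and of single-probe dye effects, that across replicate numbers, and the values per replicate number, were chosen after the results were seen. Many ribosomal protein and chaperone genes had log2 ratios of NOX10 over GT of opposite sign in the 2 replicate numbers. The ratio was positive in replicate 1 and negative in replicate 2 for 23 of 30 ribosomal protein genes and 11 of 13 chaperone genes, and had the same sign in both for 7 and 2. The median log2 ratio of the 30 ribosomal protein genes was 0.53 in replicate 1 and -0.54 in replicate 2. The 13 chaperone genes had medians of 0.57 and -0.95. Among these, the chaperonin genes groES (slr2075), groEL1 (slr2076) and groEL2 (sll0416) had ratios of 2.17, 2.06 and 1.71 in replicate 1 and -1.87, -1.64 and -1.24 in replicate 2. The small heat shock gene hspA (sll1514) had ratios of 0.99 and -3.41. The median chaperone difference of sample 2 from sample 1 was 0.67 in GT (13 of 13 higher) and -1.23 in NOX10 (8 of 13 lower). For ribosomal proteins it was 0.44 in GT (24 of 30 higher) and -0.69 in NOX10 (28 of 30 lower). These genes were picked after their values were seen, and neither the difference between replicates nor a cause was tested.

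Ratios of genes of nitrate and cyanate use are given for each replicate number. The log2 ratio was -0.19 in replicate 1 and 2.88 in replicate 2 for nrtA, -1.02 and 1.83 for nrtB (sll1451), -0.33 and 2.45 for nirA, and -0.44 and 2.12 for cynS (slr0899), which encodes cyanase. It was -0.33 and 0.011 for nrtC (sll1452), -0.36 and -0.62 for nrtD (sll1453) and -0.044 and 0.48 for narB (sll1454). These genes were picked after their values were seen, and the difference between replicates was not tested. The 20 NtcA-activated genes had a median ratio of -0.22 in replicate 1 and 0.81 in replicate 2.

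The first pattern weighed was the 123 genes called between groups of different dye. Before normalization, a loess curve of the Cy5 over Cy3 difference on mean intensity accounted for 0.492% of their squared fold change. These genes were called after normalization, in both directions, so a low percentage was likely in advance. The largest shift along the curve was 0.213, against at least 0.96 in the called genes after normalization. That argues against a smooth trend with intensity as the whole cause. After cyclic loess 63 of the 123 stayed called and all 123 kept their direction, and the cause of the loss was not tested. Dye effects of single probes would not be shared by neighbours, and fold changes of genes with consecutive locus tags correlated with r = 0.416 over 2168 pairs (rho = 0.391, at most 0.0591 in 1000 random pairings). For the called genes this leaves such effects open, since the same pairs also correlated in the difference between the 2 NOX10 samples (r = 0.333) and between the 2 GT samples (r = 0.127), where dye and genotype do not differ. Over all genes, the log ratio of a gene in one replicate number and that of its neighbour in the other, which share no sample, had r of 0.238 and 0.268 (at most 0.0747 in random pairings), which argues against single-probe dye effects as the whole cause of ratios found in both numbers. Genotype and a likeness in base composition of neighbouring genes remain open, untested because no dye was swapped and no sequence was used here.

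The second pattern was this likeness of neighbours, which a spotted array could give by position if adjacent loci were printed side by side. The difference in log ratio between the 2 spots of a gene had an r of at most 0.0481 over the same pairs, against 0.367 and 0.440 for the log ratio in replicates 1 and 2, which argues against position on the array as far as it acts on one spot of a gene. A position effect common to both spots stays open, since spot positions were not used here, as does transcription of adjacent genes as one unit, a hypothesis not tested. Neighbours were also alike in the differences within a strain, given above. Genes are not independent replicates in these correlations.

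Over all genes the SD of the log2 ratio was 0.542 in replicate 1 and 0.643 in replicate 2, while ntcA itself had ratios of 2.70 and 2.61. No explanation was tested for this difference.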
